A study of Homo sapiens with 2 samples.

How the data were processed

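The series holds HiChIP libraries of SMZ1, a T-cell lymphoma cell line. HiChIP joins DNA ends that lie close together in fixed nuclei, recovers the joined fragments with an antibody and sequences both ends, so that each read pair links a pair of genomic positions. Here the antibody was against acetylated lysine of histone H3 (H3K27ac), a mark of active promoters and enhancers, as the series description states. The labels' protocols name the published HiChIP procedure and a tagmentation enzyme kit. There were 2 samples in 1 group, numbered replicate 1 and replicate 2 in their titles. The labels do not say whether they came from separate cultures.

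Per the submitters' processing notes the reads were handled with HiC-Pro and the genome build was hg19. The HiC-Pro version, the tool that set the anchors, the tool that counted pairs between them and the duplicate filter are not given in the sources used here. Each library had its own deposited list and the authors did not pool the libraries in these files. Each list had 8 columns, with 0 header lines: the positions of both anchors, a count and a further value. The deposited count was a whole number of read pairs per pair of anchors and was not scaled to depth. The last column held a value from 0 to just under 1, treated here as a p-value or q-value assigned by the authors. The files do not say which it is, so it is called the deposited value throughout, and it was used only to describe and filter loops within a list. A pair of anchors in a list is called a loop, whatever its count. All positions are hg19 and 1-based.

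No gene annotation of hg19 was used here. The available gene table was of the GRCh38 assembly, and positions were not moved between builds. Loops were therefore not assigned to genes, promoters or distal elements, and regions are named by position. The planned results on promoter classes, loops per gene, gene lists, skipped promoters and the loci of the fusion genes were not made for that reason. The rule for the regions named was fixed before the data were examined: the 5 loops in both lists with the highest mean read-pair count, the 5 anchors with the most loops after overlapping anchors of both lists were joined, and the 10 windows of 1 Mb with the most loops. A loop was placed in a window by the point midway between its anchors.

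The depth was 300438 read pairs within loops in replicate 1 and 274742 in replicate 2. The mean was 3.02 and 2.90 read pairs per loop, so most single loops had wide counting error. Intervals are exact binomial intervals for shares and exact Poisson intervals for counts, at the 95% level. They cover counting error only.

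A loop counted as shared when each of its anchors overlapped the matching anchor of a loop in the other list by at least 1 bp. Chance was measured by moving replicate 1 along the chromosome by 1 Mb. Correlations were computed across loops, which are not independent replicates, and have no p-value. To test the lists against sampling noise, the 11323 loops with identical anchors in both were taken, and a chi-square test was run on those with at least 20 read pairs in sum, and on totals per chromosome and per span class. Neither these loops nor their totals differed by more than sampling noise, and the labels name no separate cultures. The lists were therefore counted as 1 sample, and values are given per list with no SD over replicates. That choice rests on loops whose anchors agree, and does not mean that the whole lists differed by sampling noise alone.

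To set contact counts against span, all pairs of joined anchors present in both lists and lying 5 kb to 2 Mb apart were formed, 303353 in total, with a count of 0 where no loop was listed. The contact level of a region is the sum of observed read pairs over the sum expected from the genome-wide mean at the same span, in span classes of 0.1 log10 units. It was computed, and chromosome 17 divided at 10 Mb, after the density of loops and the levels along the chromosomes had been seen. Windows of 5 Mb with at least 50 possible pairs were kept. The Y chromosome was left out of the values per chromosome.

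The steps were tested on simulated data. In a copy of replicate 1 that kept 60.0% of the loops with shifted anchor edges, 60.0% were found again. The shifts were smaller than the narrowest anchor, so no overlap could be lost. That simulation does not cover anchors that are split or missing in a list. With a 1.5-fold level put into a stretch of chromosome 2, the contact level over the 303353 possible pairs came out at 1.50 (SD 0.018 over 20 draws). That stretch is too small to move the genome-wide mean much. The parts of chromosomes 1 and 17 with high levels hold 24346 and 26575 possible pairs and raise their own expected counts. The simulation does not cover that. The alternatives were a support filter at the median, equal list lengths, looser and stricter anchor matching, shared loops only and each list alone, all chosen before the data were examined. Count minimums, bounds on the deposited value, matching on anchor density and anchors of each list alone were added afterwards. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, networkx 3.6.1 and matplotlib 3.10.9 were used.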

Results

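The H3K27ac HiChIP data covered contacts recovered with an antibody against this mark in SMZ1 cells, a T-cell lymphoma line. Whether both anchors of a loop were acetylated was not examined. The stated purpose of the experiment was to find which enhancers and promoters touch each other. The study compared no conditions in these libraries. The comparisons available were between the 2 lists, between spans and between regions of the genome. Replicate 1 listed 99627 loops with 300438 read pairs, and replicate 2 listed 94590 loops with 274742 read pairs. The loops of replicate 1 joined 22560 anchors of median width 2606 bp, and those of replicate 2 joined 22515 anchors of median width 2571 bp. All loops lay within a chromosome, and none was longer than 2 Mb, so contacts between chromosomes or over longer distances could not be seen.

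Most listed loops rested on very few read pairs. A single read pair supported 56.8% of the loops of replicate 1 (95% exact binomial interval 56.5% to 57.1%) and 58.2% of those of replicate 2 (57.9% to 58.5%). At least 10 read pairs supported 5262 loops (5.28%) in replicate 1 and 4670 loops (4.94%) in replicate 2. The median span was 243 kb in replicate 1 and 241 kb in replicate 2, with quartiles of 84.7 and 593 kb and of 83.0 and 589 kb. This median depended on which loops were counted: in the mean of the lists it was 138 kb for shared loops, 104 kb with at least 2 read pairs and 582 kb with a deposited value of at most 0.05. Weighted by read pairs, the median span was far shorter, at 66.7 and 67.6 kb. Loops of 5 to 10 kb made up 2.36% and 2.46% of the lists and held 12.3% of the read pairs in each, whereas loops of 1000 to 2000 kb made up 12.5% of each list and held 4.73% and 4.88% of the read pairs.

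Contact frequency fell with span in nearly the same way in both lists. Among anchors present in both, 97.1% of the possible pairs 5 to 10 kb apart were looped in each list, with 18.5 and 17.4 read pairs per possible pair. At 100 to 200 kb, 59.6% and 57.0% were looped, with 1.73 and 1.62 read pairs per possible pair. At 1000 to 2000 kb, 7.35% and 6.91% were looped, with 0.0855 and 0.0800 read pairs per possible pair. From 20 kb to 1 Mb the slope on log axes was -1.01 in each list. It averages a curve that grew steeper with span. In replicate 1 the count per possible pair fell from 8.03 at 22484 bp to 1.41 at 178953 bp and 0.167 at 896150 bp. These are values over possible pairs of anchors and do not include loops at anchors found in a single list.

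**Figure D1:**
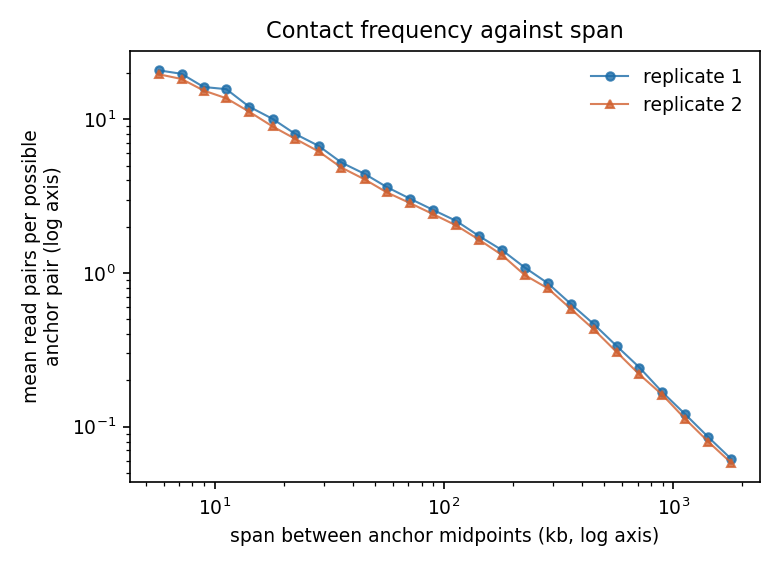
Mean read pairs per possible anchor pair (vertical, log axis) against the span between anchor midpoints in kb (horizontal, log axis), with circles for replicate 1 and triangles for replicate 2. Both curves fall together, from 20.8 and 19.6 read pairs in the shortest span class drawn to 0.0617 and 0.0582 in the longest. The partly filled first and last span classes are not drawn.

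The share of loops found in both lists rose with the read-pair count and was lowest for the longest loops. In replicate 1, 41562 loops (41.7%, 95% exact binomial interval 41.4% to 42.0%) had a partner in replicate 2, against 420 (0.422%) after a move of 1 Mb, which takes the anchors off each other and so measures shared anchors more than shared loops. In replicate 2, 41634 loops (44.0%, 43.7% to 44.3%) had a partner. The share depended on the matching rule and was 11.7% in the mean of the lists when identical anchors were required. Of loops with 1 read pair, 25.8% and 28.4% were shared. Of loops with 20 to 49 read pairs, 89.0% and 88.9% were shared. Loops of 10 to 20 kb were shared in 64.0% and 65.9% of cases and loops of 1000 to 2000 kb in 14.4% and 15.2%. Anchors limited the overlap too. Of the anchors, 75.7% and 75.9% overlapped an anchor of the other list, and 9567 anchors had identical edges in both. Where both anchors of a loop were present in the other list, 56.2% of the loops of replicate 1 and 58.7% of those of replicate 2 were shared. Among possible pairs of anchors present in both lists, 41147 were looped in both, against 32721 expected at the same span if the lists were independent, a ratio of 1.26. At 5 to 10 kb, 1449 were looped in both against 1448 expected, and at 10 to 20 kb the ratio was 1.01: there nearly all pairs were looped in each list. At 1000 to 2000 kb the ratio was 2.49.

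Across the 40268 loops with a single partner, the read-pair counts correlated with a Pearson r of 0.74 on the log2 scale and a Spearman rho of 0.638. The Pearson r was 0.80 for spans of 5 to 20 kb and 0.43 for spans of 500 to 2000 kb, where nearly all counts were small. Where the anchors were identical, the counts differed by no more than counting error. Over 897 such loops with at least 20 read pairs in sum, the chi-square was 1.02 per degree of freedom (chi-square test, p = 0.329). The totals of the 11323 loops with identical anchors did not differ in their distribution over 24 chromosomes (chi-square test, p = 0.835) or over 8 span classes (chi-square test, p = 0.396). In simulated counts, a further spread of 10% in each library raised the chi-square to 1.21 per degree of freedom, and a spread of 20% raised it to 1.80. At identical anchors the lists thus differed by about as much as sampling noise gives, and they were counted as 1 sample, with no spread over replicates. The test takes only loops whose anchors agree. On joined anchors, the contact level of chromosome 1 before its anchor-free stretch had counting intervals that do not overlap (0.8694 to 0.9032 and 0.8340 to 0.8685). Those of the other parts of chromosomes 1 and 17 and of chromosomes 3, 10 and 21 overlapped. Intervals were computed for no other part, so the lists may differ elsewhere too. Chromosome 14, for example, had levels of 1.003 and 0.940. The test does not cover the anchors and loops found in a single list, and it does not show that both lists came from 1 library.

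**Figure D2:**
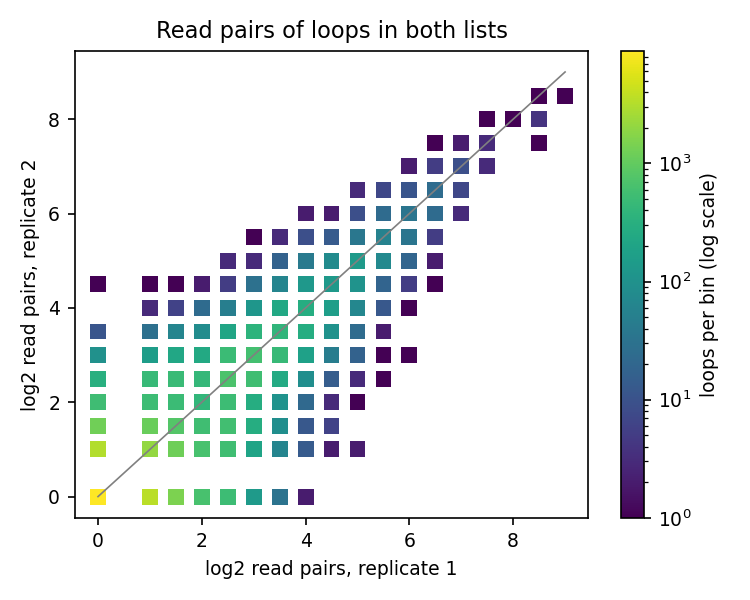
Log2 read pairs of loops with a single partner, in replicate 1 (horizontal) and replicate 2 (vertical), in bins coloured by the number of loops on a log scale. The grey line marks equal counts. The 40268 loops scatter around it, with a Pearson r of 0.74.

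The loops in both lists with the highest counts were short, and most lay on chromosome 1. The loop with the highest mean count joined chromosome 1, 192501865 to 192511635, to 192513379 to 192520685, with 538 read pairs in replicate 1 (95% exact Poisson interval 493 to 585). In replicate 2 the second anchor was narrower (192513743 to 192519583) and the loop had 341 read pairs (306 to 379). The next entries were a single loop of replicate 1 between 212850400 to 212857528 and 212861509 to 212871111 on chromosome 1, with 565 read pairs (519 to 614). Replicate 2 held it as a pair of loops from narrower anchors, at 212855879 to 212857528 with 227 read pairs and at 212850400 to 212853197 with 208. The loop between 224923192 to 224931132 and 224932207 to 224936722 on chromosome 1 had 389 read pairs in replicate 1 (351 to 430). In replicate 2 its second anchor began at 224932032 and it had 351 read pairs (315 to 390). On chromosome 17, the loop from 25784313 to 25788756 to 25789616 to 25796827 had 270 read pairs in replicate 1, and 404 in replicate 2, where the second anchor reached 25802378. All of these loops had a deposited value of 0. Spans ran from 6.69 to 14.5 kb, and the anchors of each loop lay close to each other. The ranking used raw counts, matched on neither span nor anchor width. It therefore favoured short loops, and wide anchors may be favoured too. The rank does not say how far these loops exceed other pairs of like span and width. Where the anchor edges differed between lists, the counts covered different widths and are not directly comparable.

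Contacts were spread unevenly over anchors. An anchor had a median of 7 loops in each list, and the highest numbers were 67 and 64. Anchors with at least 20 loops numbered 1766 in replicate 1 (7.83%) and 1525 in replicate 2 (6.77%). The anchor with the most loops lay on chromosome 17 at 38715925 to 38722621. It had 67 loops with 708 read pairs in replicate 1 and 64 loops with 662 read pairs in replicate 2, and 44 partners were present in both lists. Its loops ran to both sides, 40 toward lower and 27 toward higher positions in replicate 1 and 33 and 31 in replicate 2, and reached as far as 1880 kb and 1957 kb. Its strongest partner was at 38752189 to 38757893 in replicate 1 (92 read pairs) and at 38686269 to 38689671 in replicate 2 (85 read pairs).

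**Figure D3:**
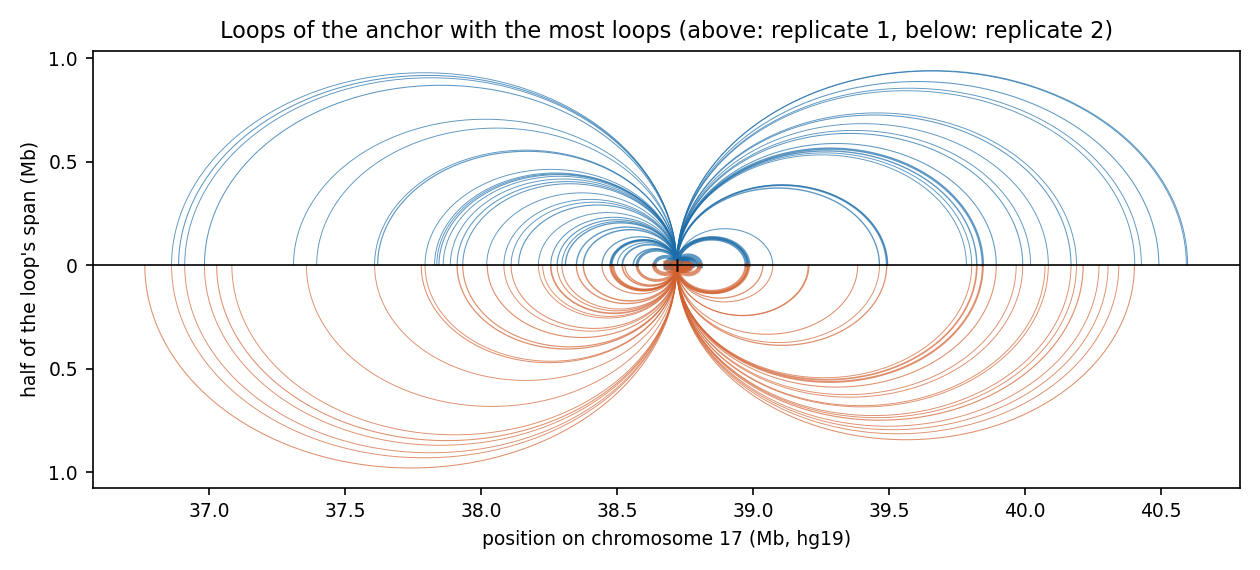
Loops of the anchor on chromosome 17 at 38715925 to 38722621, drawn as arcs over position in Mb (hg19), with replicate 1 above and replicate 2 below the line. The vertical axis is the height of an arc, which grows with the span of a loop, in Mb, and thicker arcs have more read pairs. The 67 loops of replicate 1 and the 64 of replicate 2 run to both sides of the anchor.

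Of the next 4 anchors, a pair lay near the end of chromosome 17. The anchor at 79631775 to 79634863 had 59 loops in each list, with 247 and 228 read pairs. The anchor at 80305006 to 80310118 had 55 and 62 loops, with 329 and 312 read pairs. The anchor at 32404612 to 32408733 on chromosome 6 had 60 and 52 loops but only 210 and 170 read pairs, and more of its loops ran toward higher positions (40 against 20 in replicate 1 and 37 against 15 in replicate 2). The anchor at 172307293 to 172315618 on chromosome 1 had 40 loops with 383 read pairs in replicate 1, and 69 loops with 323 read pairs in replicate 2. No single anchor of replicate 2 had more than 64 loops, so this joined anchor held more than a single anchor of that list. The loop numbers of the lists are therefore not directly comparable there, and the read pairs were lower in replicate 2.

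At the scale of 1 Mb, loops were densest in a small number of windows. Of 2529 windows with a loop, the median held 17.5 loops in the mean of the lists. The 10 densest windows held 4.80% and 4.66% of all loops, and 3 of them were on chromosome 17, 2 on chromosome 1 and 2 on chromosome 6. Chromosome 17 from 80 to 81 Mb held 659 and 636 loops over 50 and 48 anchors. Chromosome 6 from 26 to 27 Mb held 489 and 547 loops, and 416 and 373 from 32 to 33 Mb. Chromosome 16 from 30 to 31 Mb held 522 and 453. Chromosome 1 held 471 and 444 loops from 155 to 156 Mb, and 487 and 379 from 161 to 162 Mb. Chromosome 17 held 461 and 407 loops from 38 to 39 Mb, and 457 and 407 from 79 to 80 Mb. Chromosome 19 from 1 to 2 Mb held 410 and 380, and chromosome 11 from 65 to 66 Mb held 409 and 378. Dense loops did not always go with a contact level above 1, the genome-wide mean at the same span. The 5-Mb windows around those on chromosomes 16, 19 and 11 had levels below 1 (0.672 and 0.707, 0.617 and 0.591, 0.894 and 0.935). So did that around chromosome 17 from 80 to 81 Mb (0.835 and 0.885), whereas those around the remaining windows lay above 1. Between the lists, the loop numbers of all windows had a Spearman rho of 0.955.

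Of the 10 windows with the most loops, 4 were also among the 10 with the most read pairs: chromosome 1 from 161 to 162 Mb, chromosome 17 from 38 to 39 Mb and from 80 to 81 Mb, and chromosome 6 from 26 to 27 Mb. By read pairs, the first was chromosome 1 from 198 to 199 Mb, with 2946 and 3030 read pairs in 331 and 436 loops. It was followed by chromosome 17 from 45 to 46 Mb, with 3095 and 2573 read pairs in 325 and 305 loops, and chromosome 1 from 192 to 193 Mb, with 2804 and 2198 read pairs in 242 and 225 loops. Chromosome 17 from 80 to 81 Mb, the densest window when all loops were counted, ranked 8 by read pairs. When loops with at least 2 read pairs were counted, 7 of the 10 windows remained among the 10 densest, and 4 remained when loops with a deposited value of at most 0.01 were counted. The densest window changed under most filters. It was chromosome 6 from 26 to 27 Mb with at least 2 read pairs or with shared loops only. On chromosome 1 it was 161 to 162 Mb with at least 4 read pairs, and 198 to 199 Mb with a deposited value of at most 0.01. With a deposited value of at most 0.05 it stayed chromosome 17 from 80 to 81 Mb (309 loops in the mean of the lists).

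Chromosomes 1 and 17 were over-represented and chromosome 10 was sparse. Chromosome 1 held 14.3% and 15.0% of loops and 17.5% and 18.0% of read pairs, with 11.2 and 10.8 loops per anchor. Chromosome 19 had 12.3 and 11.7 loops per anchor, but its contact level was 0.685 and 0.667. Chromosome 17 held 8.92% and 8.80% of loops and 11.4% and 11.1% of read pairs, with 14.6 and 13.8 loops per anchor. Chromosome 10 held 1195 and 1073 loops and 0.915% and 0.885% of read pairs, with 4.13 and 3.85 loops per anchor. Chromosome 3 held 5.54% and 5.59% of loops, and its contact level was 0.917 and 0.935.

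The contact level, observed over span-matched expected read pairs, separated parts of chromosomes. Chromosome 1 had no anchors from 120801658 to 143742465. Beyond that stretch the level was 1.82 in each list (95% exact Poisson intervals 1.80 to 1.84), and before it the level was 0.886 and 0.851. Of 22 windows of 5 Mb beyond the stretch, 17 had a level above 1, against 7 of 22 before it. The expected counts are a genome-wide mean that includes the high parts, so a level somewhat below 1 is not in itself a depletion. On chromosome 3, with a level of 0.917 and 0.935, 7 of 35 windows had a level above 1. The highest levels of any 5-Mb window were on chromosome 1, at 4.92 and 4.61 from 190 to 195 Mb, at 3.66 and 3.87 from 195 to 200 Mb and at 3.94 and 3.26 from 210 to 215 Mb. On chromosome 17 the level was 0.391 and 0.424 before 10 Mb and 1.52 and 1.51 beyond it, a division chosen after the levels had been seen. The level did not step up at that position: it was 0.539 and 0.565 from 10 to 15 Mb, and 10 of the 15 windows beyond 10 Mb had a level above 1. The other 4 windows below 1 were at 20 to 25 Mb (0.747 and 0.952), 55 to 60 Mb (0.521 and 0.607), 60 to 65 Mb (0.703 and 0.654) and 80 to 85 Mb (0.835 and 0.885), where the 1-Mb window with the most loops lies. On chromosome 10 it was 0.528 and 0.529, and 0 of its 17 windows exceeded 1. Chromosome 21 had a level of 1.38 and 1.41. Differences between these parts were larger than the counting intervals, which do not cover spread between lists or cultures. For chromosome 1 before the stretch the intervals of the lists did not overlap. No test over replicates was made because the lists were counted as 1 sample.

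**Figure D4:**
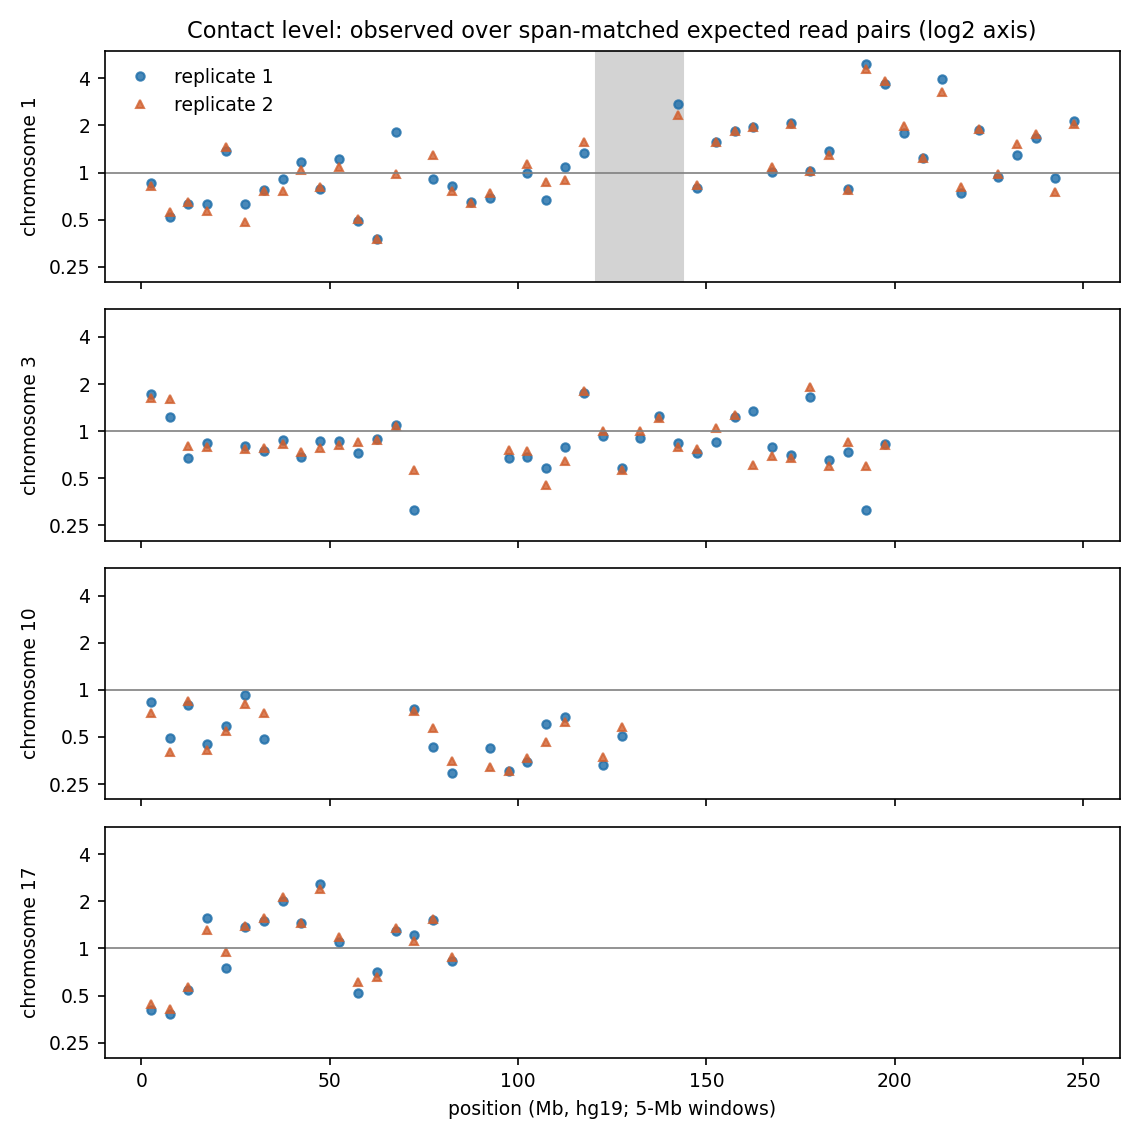
Contact level (observed over span-matched expected read pairs, log2 axis) in 5-Mb windows along chromosomes 1, 3, 10 and 17 (position in Mb, hg19), with circles for replicate 1 and triangles for replicate 2. The line marks 1 and the grey band the stretch of chromosome 1 without anchors. The level is 1.82 over the part of chromosome 1 beyond the band, and all 17 windows of chromosome 10 lie below 1.

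The deposited value was at most 0.05 in 50265 loops of replicate 1 (50.5%) and 48489 of replicate 2 (51.3%), and at most 0.01 in 15866 and 14589. Of the loops with a value of at most 0.05, 60.7% and 62.5% rested on 1 read pair, and none of the loops with a value of at most 0.01 did (0 in each list). All loops of 500 kb or more had a value of at most 0.05 (100% in each list), against 7.17% and 7.31% of loops of 50 to 100 kb. In the opposite direction, 1120 loops of replicate 1 and 794 of replicate 2 with at least 10 read pairs had a value above 0.05, and their median span was 12.6 and 11.8 kb.

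**Figure D5:**
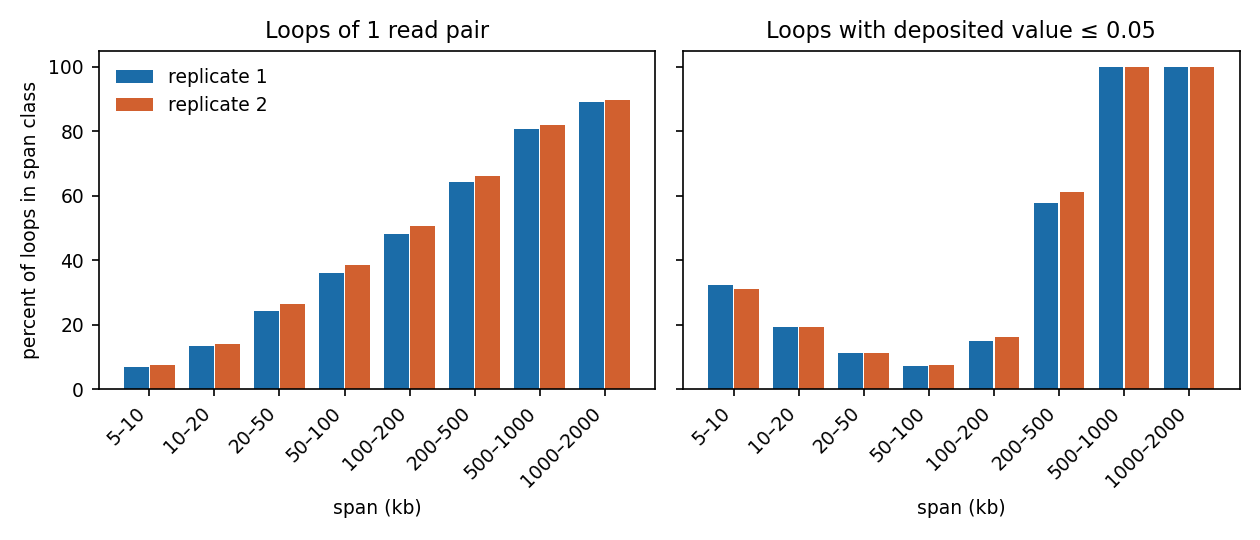
Percent of loops in each span class (kb) that rest on 1 read pair (left) and that have a deposited value of at most 0.05 (right), for replicate 1 and replicate 2. Loops of 1 read pair rise with span to 89.2% and 89.7% at 1000 to 2000 kb, and all loops of 500 kb or more have a value of at most 0.05.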

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

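The median read-pair count of each list was 1, so the planned filter at the median removed no loop and tests nothing. For the named loops, anchors and windows and the contact levels of chromosome 1 before its anchor-free stretch and chromosome 17 before 10 Mb, read pairs and levels were held against their counting interval and loop numbers against a 1.5-fold bound. With list lengths made equal by removing only loops of 1 read pair from replicate 1, which tests little, all 22 stayed within these. Outside them were 15 with loops in both lists, 17 each with at least 2 and 4 read pairs and with a value of at most 0.01, and 11 with a value of at most 0.05, all of them lower. Chromosome 17 before 10 Mb (0.407) fell in that order to 0.332, 0.340, 0.269, 0.104 and 0.203, and rose to 0.488 with the anchors of each list alone. With either list alone 17 stayed within them. The bound is loose, since the mean compared contains that list: the anchor at 172307293 passed with 40 and 69 loops. The other 5 were the named loops at 192501865, 212850400 (both entries) and 25784313, whose anchor edges differed, and chromosome 1 before the stretch (0.851 to 0.886). The count minimums, bounds on the deposited value and other anchor sets were chosen after the data were seen. The mean number of loops per list was 97109. It fell to 41598 with loops in both lists, 41283 with at least 2 read pairs, 17030 with at least 4, 49377 with a deposited value of at most 0.05 and 15228 with a value of at most 0.01, by construction. The median span (main value 242 kb) was 253 kb with equal list lengths, 138 kb for loops in both lists, 104 and 49.98 kb with at least 2 and 4 read pairs, and 582 and 334 kb with a value of at most 0.05 and 0.01. A count minimum thus favoured short loops and the deposited value long ones. The shared percentage (mean 42.9%) was 42.1% with equal list lengths, 49.9% with anchors up to 5 kb apart, 11.7% with identical anchors, 49.9% and 56.8% with at least 2 and 4 read pairs, and 30.0% and 37.1% with a value of at most 0.05 and 0.01. The Pearson r (0.74) was 0.75 with equal list lengths, 0.72 with anchors up to 5 kb apart, 0.75 with identical anchors, 0.76 and 0.77 with at least 2 and 4 read pairs, and 0.89 and 0.91 with a value of at most 0.05 and 0.01. The contact level of chromosome 1 beyond its anchor-free stretch (1.82) was 1.96 with loops in both lists, 1.96 and 2.14 with at least 2 and 4 read pairs, 2.27 and 2.63 with a value of at most 0.05 and 0.01, 1.77 when matched on anchor density as well, and 1.65 with the anchors of each list alone. In the same order chromosome 17 beyond 10 Mb (1.52) had 1.64, 1.64, 1.80, 1.77, 2.02, 1.49 and 1.54, and chromosome 10 (0.529) had 0.474, 0.482, 0.411, 0.305, 0.221, 0.575 and 0.562. No contact level crossed 1 under these settings. Filters on count, deposited value or sharing keep more read pairs where counts are high. They tend to push levels away from 1, so they hardly test on which side of 1 a level lies. Other causes of the moves were not tested. With either list alone the levels were 1.82 for chromosome 1, 1.51 to 1.52 for chromosome 17 and 0.528 to 0.529 for chromosome 10, the loops per list were 94590 to 99627 and the median span 241 to 243 kb. Other promoter windows, all transcripts and unmatched random gene lists, planned beforehand, were not run for want of an hg19 annotation. With 1 group no paired analysis was possible. Depth was not varied. Loops of 500 to 1000 kb averaged 1.31 and 1.29 read pairs, and those of 1000 to 2000 kb 1.14 in each list.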

Other observations

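The 3024 pairs of joined anchors with at least 10 read pairs in each list fell into 1099 connected groups, of which 646 (58.8%) were single pairs and 162 had at least 5 anchors. Of these larger groups 32 were on chromosome 1 and 22 on chromosome 17. The 10 groups with the most anchors are given here. A group on chromosome 3 from 4846143 to 5098392 linked 18 anchors within 252 kb by 41 strong loops, with 778 and 777 read pairs. A group of 18 anchors on chromosome 17, from 38473989 to 39846640, contained the anchor with the most loops and had 25 strong loops with 829 and 781 read pairs. On chromosome 1 a group of 13 anchors from 198125092 to 198907509 had 38 strong loops with 1861 and 1891 read pairs, and a group of 14 anchors from 192446337 to 193092713 had 28 strong loops with 1861 and 1556 read pairs. A group of 15 anchors lay on chromosome 1 from 172307293 to 172696832 (728 and 757 read pairs). Other groups of 14 anchors lay on chromosome 1 from 162602208 to 163245686 (807 and 726 read pairs) and on chromosome 17 from 80173130 to 80479285 (344 and 367 read pairs). Other groups of 13 anchors lay on chromosome 1 from 117098654 to 117604733 (494 and 563 read pairs) and from 173401386 to 174145452 (538 and 415 read pairs), and on chromosome 6 from 149352294 to 149817844 (604 and 592 read pairs). Of the 10 windows of 5 Mb with the highest contact levels, those away from chromosomes 1 and 17 were on chromosome 2 from 180 to 185 Mb (3.58 and 3.18) and from 135 to 140 Mb (3.12 in each list), on chromosome 7 from 50 to 55 Mb (2.49 and 3.17), on chromosome 21 from 25 to 30 Mb (2.46 and 2.93) and on chromosome 18 from 50 to 55 Mb (2.47 and 2.23).

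The tests of anchor spacing, of chromosome 17 and of the deposited value against span were chosen after the result was seen. The others were set before their result was seen. The high contact level on chromosome 1 beyond its anchor-free stretch may come from more DNA copies of that part in SMZ1. Closer spacing of anchors as the whole cause was argued against by the level of 1.77 that was left after matching on anchor density as well as span (1.82 with span alone), and a few strong loci by the level of 1.49 that was left without the highest 6 of the 22 windows, against 0.715 before the stretch with the same trimming. Extra copies should raise weak contacts as well, and pairs 1 to 2 Mb apart had a level of 1.67 (1603 and 1547 read pairs). Matched on anchor density as well, that level was 1.76. Under 100 kb the level was higher, at 1.92, so extra copies alone may not account for all of it. Stronger acetylation over the whole part would also raise the contact level and stays open, since no coverage of unselected DNA was used here. On chromosome 17 beyond 10 Mb, extra copies cannot be told apart from stronger local contacts: the level was 1.76 under 100 kb but 1.03 at 1 to 2 Mb, and 1.16 there when matched on anchor density as well.

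Lone read pairs over long spans carried deposited values of at most 0.05. Across loops of 1 read pair the value followed the span with a Spearman rho of -0.989 in the mean of the lists, and the shortest such loop with a value of at most 0.05 spanned 348 kb in replicate 1 and 330 kb in replicate 2. They also recurred more often than span alone would give. Between anchors of both lists, 24.2% and 26.6% recurred in the other list. Of all possible pairs of the same span 15.5% and 17.1% did, a ratio of 1.56 in the mean. All loops together also exceeded independence, by 1.43 at 200 to 500 kb, 1.87 at 500 to 1000 kb and 2.49 at 1000 to 2000 kb. The ratio is thus not particular to lone read pairs with a low value. A candidate explanation is that the value measures how improbable a read pair is at its distance. What makes these loops recur was not tested. Since the lists may be a single library, recurrence does not show that such contacts would return in other cells.

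The 100 anchors with the most loops had a median width of 4343 and 4869 bp, against 2606 and 2571 bp for all anchors, so wide anchors may collect more loops simply by covering more sequence. Across all anchors the Spearman rho of width and number of loops was 0.253 in the mean of the lists, between the bounds set beforehand for and against that explanation, so the part of width cannot be told apart from stronger acetylation of wide anchors. The number of other anchors within 2 Mb had a higher rho with the number of loops, 0.545.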
